A study of Mus musculus with 6 samples.

How the data were processed

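RNA was measured in mCherry-positive neocortical cells sorted from mouse embryos at E14.5, 24 h after electroporation at E13.5, in 3 libraries from embryos given a plasmid for mCherry alone and 3 from embryos given a plasmid for Insm1 and mCherry. Per the labels' protocols, cDNA was made from total RNA with a tailed poly-dT primer and template switching, amplified for 12 cycles, sheared, made into libraries with 15 further cycles and sequenced as single 75-base reads. This kind of library marks no strand, so reads of a gene and of an overlapping gene on the other strand cannot be told apart, and it carries no molecular identifiers, so counts are of amplified fragments. Per the submitters' processing notes, bcl2fastq, TopHat2 2.0.13 and Bowtie were used with GRCm38. The counting program, its strand setting and the annotation release are not given in the sources used here.

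The deposited count table holds whole-number counts per Ensembl gene for the 6 libraries with gene symbols, and library totals between 30017645 and 31645135. The deposited TPM table holds the same genes. Its TPM values equal the authors' counts divided by 1 length per gene and scaled to one total per library, and 333 genes have no TPM. Of 22001 genes, 199 carry no symbol and are known by their identifier, 52 repeat a symbol, and 21492 identifiers are in GENCODE M21, which was used for coordinates and exon overlaps on GRCm38. The mCherry sequence and Xist and Tsix, which made up a fixed list for X inactivation, are not among the genes used here. Each library counted as 1 sample because the labels list it as one. Pairs of libraries of one group had a chi-square per degree of freedom between 12.43 and 31.05, which covers counting error only, so separately amplified libraries of one sample would exceed 1 too.

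Genes were kept by edgeR's filterByExpr, which left 13560, and scaled by TMM, with factors between 0.975 and 1.021. The Insm1 and control groups were compared by edgeR 4.0.16 (R 4.3.3) with a robust quasi-likelihood fit to group alone and a two-sided test, and genes were called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors of log2 fold changes were taken from the F statistic of that test. CPM values are TMM-scaled, and values after ± are SDs over 3 libraries. For the Insm1 and Plekha7 comparison an exact permutation test of log2 CPM was added.

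Before the data were examined, 40 gene lists that share no gene were fixed, covering cell types of the cortex, junctions, signalling, cell cycle, stress and other tissues that a sort might hold, and the 39 with at least 3 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over these lists. 20 lists were called, 9 higher and 11 lower. With a correlation estimated from the libraries camera called 0, with 5 at an unadjusted p below 0.05 and a lowest adjusted p of 0.122. The fry test called 4 lists in one direction and 24 in either direction. In 10 lists, none of them called, the list median and camera's direction differed in sign.

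Genes were named by a rule also fixed then. It takes Insm1 and Plekha7, the 12 largest rises and the 12 largest falls among called genes with a proper symbol, a mean of at least 5 CPM in either group and libraries that do not overlap, up to 4 called members of each list (or, with none called, the 2 of highest expression), the most abundant member of cell type and quality lists, and a few reference genes of the developing cortex. Other genes named as examples are members of the fixed lists and were chosen after their values were seen: Emx1, Lhx2, Neurod6 and Bcl11b in the text of the report. The rule takes 121 genes, some of which are not reported here. Of these and the 4 others, 84 were called, and 35 of the 84 were called with each library left out in turn. Some list members with too few counts to be tested are also named.

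The same fit was tested on simulated counts for the Insm1 comparison, with the means, library sizes and spread of the 13560 genes and 200 genes changed. It recovered 46.3% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 87.9% of those changed 4-fold, and called 6 unchanged genes. Each gene was drawn independently, so differences that many genes of a library share were not simulated, and these values do not cover them.

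Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), no filter, a filter at 5 CPM in 3 libraries, the replicate number as a block, each library left out, a fit that is not robust, other thresholds, and removal of the Insm1 counts.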

Results

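Neocortical cells of mouse embryos were compared after in utero electroporation, in which plasmid DNA injected into the ventricle of the embryonic brain is driven by current pulses into the cells that line it. Electroporation was at E13.5, tissue was taken 24 h later at E14.5, and cells carrying the red fluorescent protein mCherry were collected by fluorescence-activated sorting. The control plasmid encoded mCherry alone and the other plasmid encoded Insm1 together with mCherry, with 3 RNA-seq libraries in each group. Insm1 is a zinc-finger transcription factor of neural and neuroendocrine progenitors. Library totals lay between 30017645 and 31645135 counts over 22001 genes, of which 13560 had enough counts to be tested. The labels number the libraries without saying whether they came from separate litters, so the p-values measure the spread between these libraries, which may be partly technical.

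The comparison asks what forced expression of Insm1 does to the transcripts of electroporated cells, and in particular to Plekha7, a protein of the adherens junction belt that ties progenitors to each other at the ventricular surface. Insm1 rose 5.61-fold, from 308 ± 76.8 CPM (SD, n = 3) in the controls to 1726 ± 393 CPM (SD, n = 3) in the Insm1 libraries. Plekha7 fell from 14.2 ± 1.28 CPM (SD, n = 3) to 8.03 ± 1.83 CPM (SD, n = 3), which is 1.77-fold lower. For Insm1 the log2 fold change was 2.49 with a standard error of 0.26 and an adjusted p of 0.0122 in edgeR's quasi-likelihood test. For Plekha7 the log2 fold change was -0.82 with a standard error of 0.19 and an adjusted p of 0.0495, just inside the threshold of 0.05. In both genes the 3 libraries of one group lay wholly on one side of the 3 of the other, from 222 to 371 CPM against 1436 to 2173 CPM for Insm1 and from 13.4 to 15.7 CPM against 6.90 to 10.2 CPM for Plekha7. The exact two-sided permutation test of log2 CPM gave p = 0.1 for each gene, the smallest that 3 libraries against 3 allow. The Plekha7 call was kept without Insm1 library 1 (adjusted p = 0.0276) and lost without control 1 (0.114), control 2 (0.0900), control 3 (0.145), Insm1 library 2 (0.151) or Insm1 library 3 (0.159), with log2 fold changes between -1.03 and -0.73 over the 6 fits.

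On GRCm38, Insm1 (ENSMUSG00000068154) is a protein-coding gene at chromosome 2, 146221921 to 146225020, plus strand, and Plekha7 (ENSMUSG00000045659) is a protein-coding gene at chromosome 7, 116123485 to 116308376, minus strand, in the GENCODE M21 annotation. Counts for Insm1 are per gene, so transcripts of the plasmid and of the chromosomal gene are not told apart. The exons of neither gene overlap those of another gene in the table.

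**Figure D1:**
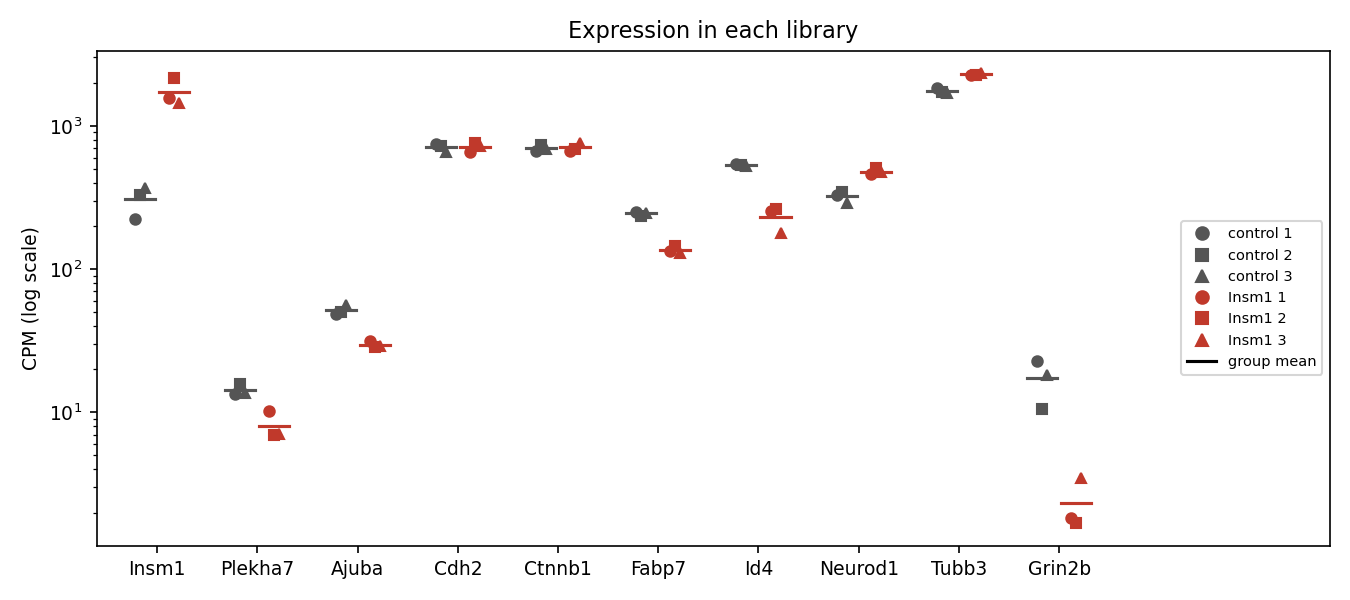
Expression of 10 genes in each of the 6 libraries, in CPM on a log axis; points are libraries, marked by replicate number and coloured by group, and horizontal lines are group means. Insm1 lies between 222 and 371 CPM in the controls and between 1436 and 2173 CPM in the Insm1 libraries, while Cdh2 and Ctnnb1 overlap between groups.

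Across the transcriptome 454 genes were called at an adjusted p below 0.05, 167 higher and 287 lower with Insm1. The lower genes changed more, with a median absolute log2 fold change of 0.882 against 0.459 among the higher ones. A log2 change beyond 1 was seen in 120 of the lower and 13 of the higher genes. The libraries of the groups did not overlap in any of the 454 genes, and over all tested genes they did not overlap in 22.2%, where chance gives 10% for 3 against 3. Without control 3 only 116 genes were called, without control 1, Insm1 library 2 or Insm1 library 3 the counts were 234, 194 and 218, and 115 of the 116, 218, 177 and 197 of these were also among the 454. DESeq2 called 424 genes higher and 592 lower, and limma on log2(TPM + 1) values 21 higher and 79 lower.

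The largest falls after Insm1 included Grin2b. This gene, which encodes a subunit of the NMDA-type glutamate receptor, fell from 17.3 ± 6.25 to 2.33 ± 0.982 CPM (SD, n = 3), 7.42-fold. The glycine receptor subunit Glra2 was 8.50-fold lower, the kainate receptor subunit Grik3 4.85-fold, the potassium channel subunit Kcnv1 8.14-fold, and the adhesion proteins Kirrel3 and Lrfn5 5.10-fold and 4.93-fold. Tmtc1 was 13.1-fold lower (log2 fold change -3.71, from -4.50 to -3.26 with single libraries left out), Sla 5.75-fold, N28178 5.27-fold, the dynein intermediate chain Dync1i1 5.25-fold, the LIM-domain-binding cofactor Ldb2 4.88-fold and the phosphatase subunit Ppp2r2c 4.53-fold. Control 2 lay below controls 1 and 3 in all 12 of these genes, for instance at 10.6 CPM for Grin2b against 23.0 and 18.3 CPM. Glra2, Grin2b, Sla, Kirrel3 and Lrfn5 were called with each library left out in turn, and the other 7 lost the call without at least 1 library.

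The largest rises after Insm1 were smaller. The claudin gene Cldn3 rose 2.21-fold, the ubiquitin ligase gene Pdzrn3 2.15-fold, the phospholipase C gene Plch2 2.14-fold and Adcyap1, which encodes the neuropeptide PACAP, 2.13-fold. Cpeb2, a translation regulator, rose 2.05-fold, Adamtsl3 2.02-fold, the calcium-activated potassium channel gene Kcnn1 2.02-fold, Nxph4 1.96-fold and the transcription factor gene Foxo1 1.93-fold, from 14.9 ± 0.228 to 28.7 ± 2.10 CPM (SD, n = 3). Ly6g6e rose 2.14-fold and shares exon sequence with Ly6g6d, and Kcnn1 shares exon sequence with A230052G05Rik, so reads of these pairs may be split or pooled. Pdzrn3, Plch2, Cpeb2, Kcnn1, Nxph4 and Foxo1 were called with each library left out, and Cldn3, Ly6g6e, Adcyap1 and Adamtsl3 were not.

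Markers of apical progenitors, the radial glia that divide at the ventricular surface, were lower as a group. Of 22 measured members 12 fell, 2 rose and 8 did not pass, or 16 lower and 2 higher adjusted over the list alone. The median log2 fold change was -0.63 and camera gave an adjusted p of 1.21e-20 for the list, with an adjusted p = 0.211 with an estimated correlation. The brain fatty acid-binding protein gene Fabp7 fell 1.80-fold, from 245 ± 8.00 to 136 ± 8.40 CPM (SD, n = 3). The glutamate transporter gene Slc1a3 fell 2.10-fold, the inhibitor of bHLH factors Id4 2.29-fold and the orphan receptor gene Nr2e1 1.59-fold. Emx1 and Lhx2, transcription factors of cortical progenitors, rose 1.31-fold and 1.27-fold. Pax6 was at 138 ± 6.65 and 128 ± 9.36 CPM (SD, n = 3; adjusted p = 0.567), and Sox2 at 115 ± 5.36 and 82.4 ± 19.0 CPM (SD, n = 3; adjusted p = 0.119), and Sox2 was called lower without Insm1 library 1 (0.0363) and by DESeq2 (0.0134). Another list, genes enriched in basal radial glia, had 4 of 8 measured members lower, none higher and 4 not passing, or 5 lower adjusted over the list alone. Its median was -0.89 (camera adjusted p = 2.65e-09, and adjusted p = 0.122 with an estimated correlation). The receptor phosphatase Ptprz1 fell 1.96-fold, Lifr and Il6st, receptors of the LIF pathway, 2.47-fold and 1.76-fold, and the matrix protein gene Tnc 2.64-fold. Fabp7, Slc1a3, Id4, Nr2e1 and Ptprz1 were called with each library left out, and Lifr, Il6st and Tnc lost the call without at least 3 of the 6 libraries, Emx1 and Lhx2 without 5.

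Markers of basal progenitors, which divide away from the ventricle, were mixed in sign, 8 positive and 7 negative, although camera called the list higher. Their mean log2 CPM was 7.01, 7.17 and 7.06 in controls 1, 2 and 3 and 7.33, 7.17 and 7.15 in Insm1 libraries 1, 2 and 3, so the groups overlapped. Of 15 measured members 4 rose, none fell and 11 did not pass. Adjusted over the list alone, 4 were higher and 1 lower. The list median was 0.15 (camera adjusted p = 0.00195, and adjusted p = 0.274 with an estimated correlation). The bHLH factor gene Nhlh1 rose 1.94-fold, from 40.9 ± 3.74 to 79.5 ± 9.55 CPM (SD, n = 3). The somatostatin receptor gene Sstr2 rose 1.5-fold and Mfng, a modifier of Notch receptors, 1.27-fold. Eomes, the T-box factor that marks basal progenitors, was at 416 ± 25.6 and 403 ± 32.9 CPM (SD, n = 3; adjusted p = 0.831), and Neurog2 at 380 ± 61.1 and 351 ± 115 CPM (SD, n = 3; adjusted p = 0.885). Nhlh1 was called with each library left out, and Sstr2 and Mfng lost it without at least 3 of the 6 libraries.

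Markers of projection neurons went both ways. Of 22 measured members 5 rose, 1 fell and 16 did not pass. Adjusted over the list alone, 13 were higher and 5 lower. The median was 0.25 (camera adjusted p = 0.00495, and adjusted p = 0.402 with an estimated correlation), and without control 2 the camera adjusted p was 0.106. The neuronal tubulin gene Tubb3 rose 1.31-fold, Neurod1 1.49-fold, Neurod6 1.24-fold and the deep-layer factor gene Bcl11b 1.19-fold. Mef2c, a factor of maturing neurons, fell 3.70-fold, from 55.3 ± 14.1 to 14.9 ± 1.5 CPM (SD, n = 3), and was at 39.8 CPM in control 2. Tbr1 was at 341 ± 25.6 and 398 ± 5.64 CPM (SD, n = 3; adjusted p = 0.101), and DESeq2 called Tbr1 higher (0.0228). Neurod1 shares exon sequence with Cerkl. In the synaptic vesicle list 2 of 12 rose and 1 fell, or 3 and 2 adjusted over the list alone. Syn2 and Rab3a rose 1.70-fold and 1.42-fold and Sv2b fell 2.62-fold. The list median was 0.0025, from -0.017 to 0.056 with single libraries left out (camera adjusted p = 0.222). In the migration list 2 of 17 rose and 1 fell, or 4 and 2 adjusted over the list alone, with a camera adjusted p of 0.856. The small GTPase gene Rnd2 and the semaphorin receptor gene Nrp1 rose 1.30-fold and 1.47-fold, and Dab1, the adaptor of reelin signalling, fell 2.60-fold, from 187 ± 34.6 to 72.0 ± 4.09 CPM (SD, n = 3). Syn2 and Rnd2 share exon sequence with Timp4 and Vat1, and Rab3a with Mpv17l2. Tubb3, Neurod1, Mef2c, Syn2, Rab3a and Dab1 were called with each library left out, and Rnd2, Nrp1, Sv2b, Neurod6 and Bcl11b lost the call without at least 4 libraries.

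Among adherens junction genes Plekha7 and Ajuba fell. Of 17 measured members 2 fell, none rose and 15 did not pass, or 3 lower adjusted over the list alone. Ajuba, a LIM protein found at junctions, fell 1.73-fold, from 51.5 ± 4.21 to 29.7 ± 1.54 CPM (SD, n = 3), with an adjusted p of 0.00536, and was called with each library left out. N-cadherin (Cdh2) was at 707 ± 49.4 and 717 ± 51.0 CPM (SD, n = 3; adjusted p = 0.934), and beta-catenin (Ctnnb1) at 697 ± 38.1 and 708 ± 49.0 CPM (SD, n = 3; adjusted p = 0.911). The list median was 0.02, from -0.0067 to 0.07 with single libraries left out, and camera, whose direction was down, gave an adjusted p of 0.561. Among apical polarity and tight junction genes, 1 of 20 measured members fell and 19 did not pass. Adjusted over the list alone, 3 were lower and 1 higher. The scaffold gene Magi1 fell 1.26-fold (adjusted p = 0.0477), and lost the call without each library except Insm1 library 1. The list median was -0.11, from -0.13 to -0.06 with single libraries left out (camera adjusted p = 0.288). Fry's mixed test, which asks only whether some members of a list differ and called 24 of 39 lists, gave adjusted p = 0.00121 and 0.00227 for adherens junction and polarity genes.

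**Figure D2:**
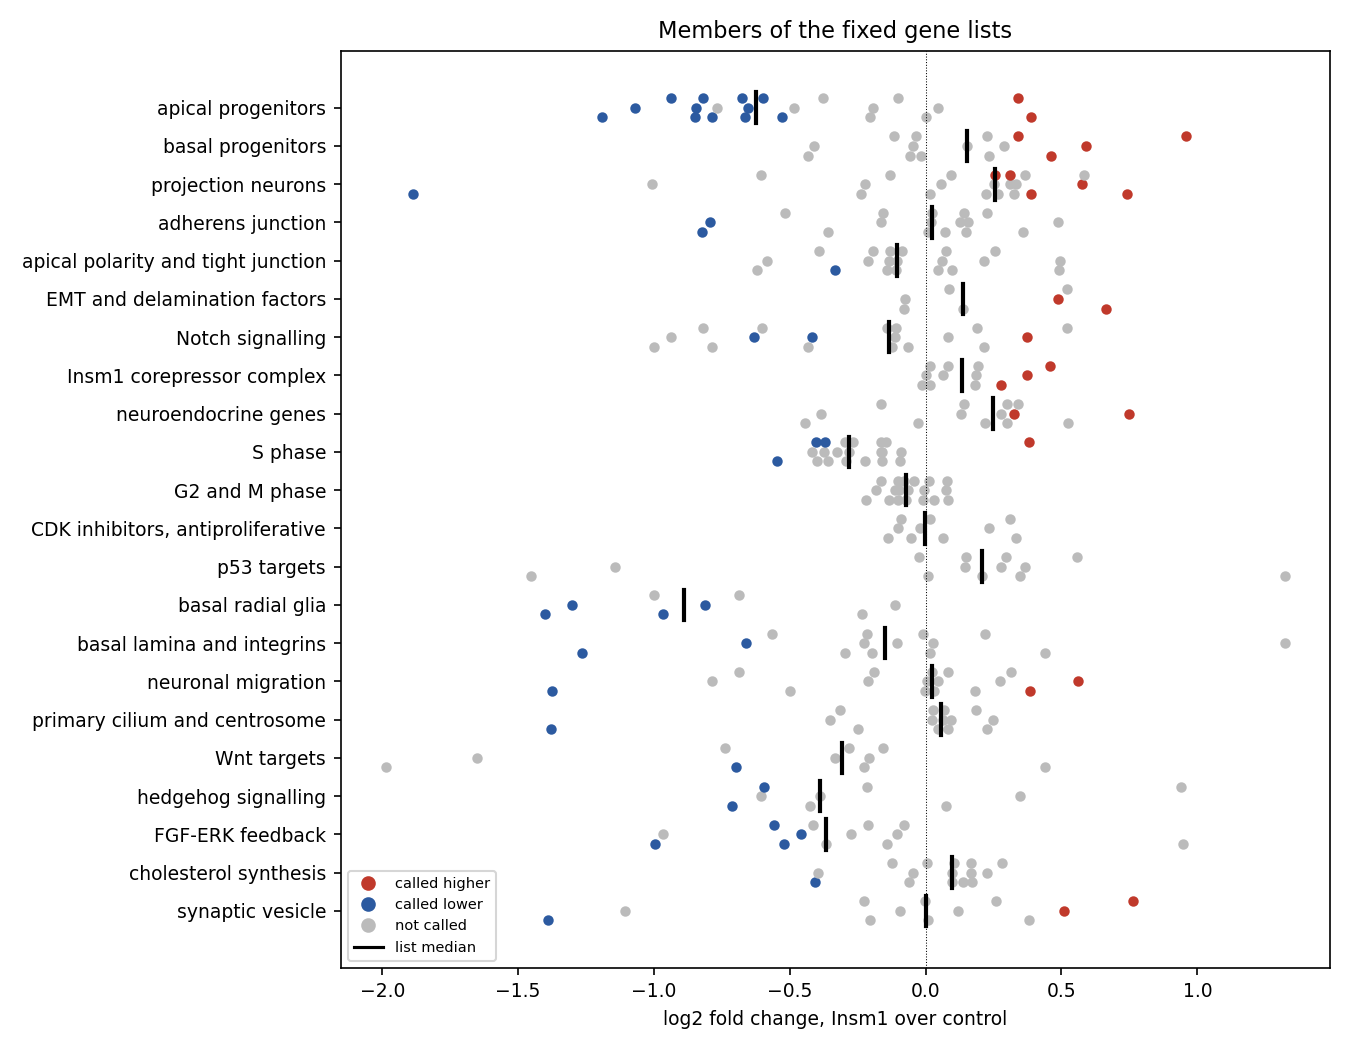
Log2 fold change (Insm1 over control) of each measured member of the fixed gene lists on cell types, junctions, signalling and cell cycle; points are genes, coloured by their call at an adjusted p below 0.05, and vertical lines are list medians. The apical progenitor median is -0.63 and that of adherens junction genes 0.02.

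In the FGF-ERK feedback list 4 of 13 fell and none rose, or 5 lower adjusted over the list alone, with a median of -0.37 (camera adjusted p = 6.70e-06, and adjusted p = 0.122 with an estimated correlation). The members that fell were the receptors Fgfr1 (1.47-fold), Fgfr2 (1.99-fold) and Fgfr3 (1.44-fold), and Spred1 (1.38-fold), an inhibitor of the ERK pathway. Fgfr2 shares exon sequence with Ctbp2. In the hedgehog list 2 of 9 fell, or 4 adjusted over the list alone, with a median of -0.39, from -0.45 to -0.21 with single libraries left out (camera adjusted p = 0.00349, and adjusted p = 0.428 with an estimated correlation). Both, Cdon (1.51-fold) and Gas1 (1.64-fold), encode co-receptors of hedgehog ligands. In the Wnt list 1 of 10 fell, or 2 adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.0204, lost without control 1 at 0.0710, and adjusted p = 0.274 with an estimated correlation). That gene was Tcf7l2 (1.62-fold). The mean log2 CPM of the Wnt list was 2.99, 2.13 and 2.92 in controls 1, 2 and 3 and 2.15 to 2.25 in the Insm1 libraries. On this scale control 2 lay below every Insm1 library, as it did for Cajal-Retzius genes. In summed CPM of the Wnt list control 2 (184) lay above every Insm1 library (134 to 154). In the Notch list the receptors Notch1 and Notch2 fell 1.34-fold and 1.55-fold and Numbl, a relative of the Notch antagonist Numb, rose 1.29-fold, so that 2 of 18 fell and 1 rose, or 5 and 2 adjusted over the list alone. The Notch list as a whole had a median of -0.13 (camera adjusted p = 0.115), called without control 3 (median -0.22, 0.0319) or Insm1 library 2 (median -0.24, 0.0195). Its target Hes1 was at 202 ± 43.0 and 114 ± 26.4 CPM (SD, n = 3; adjusted p = 0.0854), and Hes1 was called lower without control 1 (0.0473) or Insm1 library 1 (0.0476) and by DESeq2 (0.0272). Among basal lamina and integrin genes 2 of 14 fell, or 3 adjusted over the list alone. Lama1, a laminin chain, fell 2.40-fold and the integrin gene Itgb8 1.58-fold, with a list median of -0.15, from -0.19 to -0.075 with single libraries left out (camera adjusted p = 0.0334, and adjusted p = 0.428 with an estimated correlation). The call of that list was lost without control 1 (0.130), control 2 (0.0707) or Insm1 library 1 (0.178). Fgfr1, Fgfr2, Lama1 and Itgb8 were called with each library left out, whereas Fgfr3, Gas1, Cdon, Tcf7l2, Notch1 and Notch2 lost the call without at least 2 libraries, and Spred1 and Numbl without control 3 (adjusted p = 0.0563 and 0.0556).

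Genes of the corepressor complex that binds Insm1 and related proteins rose together, with 3 of 12 measured members higher, also adjusted over the list alone, and a median of 0.13 (camera adjusted p = 0.00223, and adjusted p = 0.211 with an estimated correlation). Rcor2, a CoREST protein, rose 1.37-fold, the histone demethylase gene Kdm1a 1.21-fold and Gse1 1.29-fold. Gse1 shares exon sequence with the S-phase gene Gins2, which rose 1.30-fold. In the neuroendocrine list 2 of 14 rose, or 6 adjusted over the list alone. The chromogranin gene Chga rose 1.68-fold and the secretogranin gene Scg3 1.25-fold, with a median of 0.25 (camera adjusted p = 0.00054, and adjusted p = 0.338 with an estimated correlation). The mean log2 CPM of that list was 4.40, 3.85 and 4.27 in controls 1, 2 and 3 and 4.28 to 4.44 in the Insm1 libraries. Of the factors tied to epithelial-mesenchymal transition and delamination 2 of 7 rose, or 3 adjusted over the list alone. These were Foxp4 (1.59-fold) and Scrt2 (1.40-fold), with a list median of 0.14, from 0.05 to 0.34 with single libraries left out (camera adjusted p = 0.00191, and adjusted p = 0.274 with an estimated correlation). Of the 13 fixed members Snai1, Snai2, Snai3, Twist1, Twist2 and Foxc2 had too few counts to be tested, so the list call does not cover them. Rcor2, Chga and Foxp4 were called with each library left out, and Kdm1a, Gse1, Scg3 and Scrt2 were each called in at most 2 of the 6 such fits.

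Among S-phase genes 3 of 21 fell and 1 rose, or 12 and 1 adjusted over the list alone. The replicative helicase genes Mcm3, Mcm4 and Mcm5 fell 1.46-fold, 1.32-fold and 1.29-fold, with a list median of -0.28 (camera adjusted p = 6.21e-06, and adjusted p = 0.444 with an estimated correlation). With single libraries left out Mcm4 was called in 3 of the 6 fits, Mcm3 in 2 and Mcm5 in 0. The mean log2 CPM of the list was 6.597, 6.878 and 6.702 in controls 1, 2 and 3. In Insm1 libraries 1, 2 and 3 it was 6.64, 6.364 and 6.435, so the groups overlapped. None of 19 G2 and M-phase genes passed in edgeR, none at an unadjusted p below 0.05 and none in DESeq2 or limma-voom, with a median of -0.07, from -0.22 to 0.06 with single libraries left out (camera adjusted p = 0.477, called without Insm1 library 1 at 0.00460). Mki67, the proliferation marker, was at 616 ± 114 and 561 ± 90.7 CPM (SD, n = 3; adjusted p = 0.741), and Top2a at 666 ± 108 and 664 ± 119 CPM (SD, n = 3; adjusted p = 0.993).

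Markers of other cells and tissues differed between libraries as well as between groups. Genes of the cortical hem and choroid plexus, at the medial edge of the cortex, had a median log2 fold change of -1.20, with 1 of 8 measured members lower, also adjusted over the list alone (camera adjusted p = 0.00966, lost without control 1 at a median of -0.78 and 0.0710, and adjusted p = 0.444 with an estimated correlation). That member, the R-spondin gene Rspo3, was at 32.0, 11.6 and 30.6 CPM in controls 1, 2 and 3 and at 5.45 to 7.79 CPM in the Insm1 libraries, and lost its call without 5 of the 6 libraries. All 8 measured members together summed to 44.8, 14.3 and 39.6 CPM in controls 1, 2 and 3, so Rspo3 made up most of the list. Of its 12 fixed members Ttr, Wnt3a, Folr1 and Kcnj13 had too few counts to be tested. Markers of Cajal-Retzius cells, early neurons that secrete reelin, had a median of -1.14, with none of 9 members called by edgeR, 3 at an unadjusted p below 0.05 and 2 called by DESeq2 (camera adjusted p = 0.0344, and adjusted p = 0.660 with an estimated correlation). Reln was at 102, 29.4 and 97.6 CPM in controls 1, 2 and 3 and at 27.9 to 42.8 CPM in the Insm1 libraries, so control 2 lay with the Insm1 libraries in this list, and without control 2 Reln was called lower (adjusted p = 0.000886). The Cajal-Retzius call was lost without control 1 (0.362), control 3 (0.167), Insm1 library 2 (0.0748) or Insm1 library 3 (0.0960). Erythroid genes went the other way, at a summed 757, 5515 and 326 CPM in controls 1, 2 and 3 and 5072, 5174 and 3815 CPM in Insm1 libraries 1, 2 and 3. None of 10 erythroid members was called by edgeR, at an unadjusted p below 0.05, by DESeq2 or by limma-voom (median 1.09, from 0.59 to 3.03 with single libraries left out, camera adjusted p = 0.00914, and adjusted p = 0.617 with an estimated correlation), and the list call was lost without control 3 (0.0666) or Insm1 library 1 (0.0552). Hba-a1 shares near-identical sequence with its copy Hba-a2, so its counts are uncertain. Y-linked genes summed to 3.98 CPM in Insm1 library 1 and to 59.2 to 146 CPM in the other 5 libraries. With controls 1 and 3 left out, chosen after seeing the data, edgeR called 0 genes, with 1554 at an unadjusted p below 0.05; the single control is then assumed to vary like the Insm1 libraries. In that fit the log2 fold changes were 2.39 for Insm1 (adjusted p = 0.134) and -0.96 for Plekha7 (adjusted p = 0.273).

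**Figure D3:**
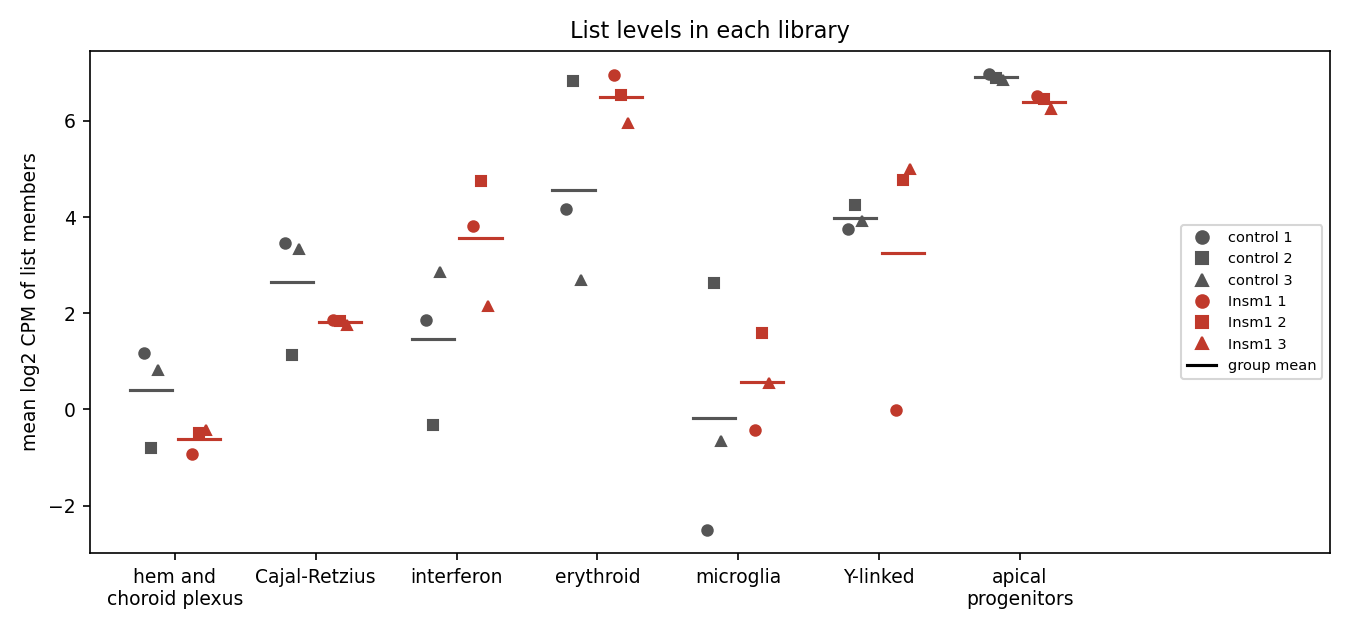
Mean log2 CPM of the measured members of 7 gene lists in each of the 6 libraries; points are libraries, marked by replicate number and coloured by group, and horizontal lines are group means. Control 2 lies near the Insm1 libraries for hem, Cajal-Retzius and erythroid genes, whereas for apical progenitor genes the 3 controls (6.85 to 6.98) lie above the 3 Insm1 libraries (6.25 to 6.51).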

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

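Every gene called in the report kept its sign in every alternative that tested it. No named gene that was called in the main fit or in an alternative reversed between the 2. Named genes called in neither did change sign, 8 of them on log2(TPM + 0.1) and 7 without control 2. Reln, for instance, was not called in the main fit and ranged from -1.53 to 0.24 over the alternatives. The lowest value was from the fit without control 2, which did call it lower. The count of 454 called genes stayed within 1.5 times under RLE (452) and upper-quartile scaling (472), limma-voom (406), no filter (496), the stricter filter (526), a fit that is not robust (426) and removal of the Insm1 counts (453). It became 1016 (424 higher, 592 lower) in DESeq2, 100 (21 and 79) on log2(TPM + 1), 96 (20 and 76) on log2(TPM + 0.1), 90 (31 and 59) at an adjusted p below 0.01, 834 (328 and 506) at an adjusted p below 0.1 and 14 (0 and 14) against a fold of 1.5 with glmTreat. For the thresholds and glmTreat the rule itself sets the count, and for the other changes the cause was not tested. With single libraries left out the counts ranged from 116 to 645 genes, 43 to 227 higher and 73 to 418 lower. Simulated 1.5-fold changes were recovered in 46.3% of genes at this depth, so smaller changes are often missed.

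The rise of Insm1 was called in every alternative planned before the data were seen, with log2 fold changes from 2.29 to 2.65 with libraries left out. Plekha7 stayed negative throughout and lost its call under RLE scaling (-0.82, adjusted p = 0.0504), on log2(TPM + 1) (-0.30, 0.0983) and log2(TPM + 0.1) (-0.75, 0.132), and in the fit that is not robust (-0.82, 0.0526), and ranged from -1.03 to -0.73 with libraries left out. It kept its call under upper-quartile scaling (0.0466), DESeq2 (0.00351), limma-voom (0.0452), no filter (0.0445) and the stricter filter (0.0332). The cause was not tested.

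With the replicate number as a block, 331 genes were called, 115 higher and 216 lower, and Plekha7 was at -0.84 (adjusted p = 0.0980). The correlations of deviations from the group means showed no clear pairing of libraries that share a number. They were 0.074, 0.035 and -0.055, against -0.097 to 0.065 for libraries of different numbers. With 3 libraries a group, large differences of single libraries can hide a pairing, so it is not excluded.

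The 20 called lists became 0 with an estimated correlation and 4 with fry in one direction, and 16 to 19 with single libraries left out. Estimated correlation left the medians unchanged and ended the calls of apical progenitors (-0.63, adjusted p = 0.211), basal progenitors (0.15, 0.274) and projection neurons (0.25, 0.402). Fry in one direction ended those of basal progenitors (0.15, 0.102) and projection neurons (0.25, 0.136), and fry in either direction called adherens junction (0.024, 0.00121) and apical polarity genes (-0.11, 0.00227). The projection neuron median ranged from 0.22 to 0.28 with libraries left out. The Y-linked median ranged from -0.15 to 0.92, and camera's direction for that list turned to higher without Insm1 library 1 (0.92, 6.64e-09), the library with few Y-linked counts.

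The last 2 alternatives were chosen after seeing the data, and why the values moved was not tested. With control 2 as the only control, Insm1 was at 2.39, Plekha7 at -0.96 and the basal progenitor median at 0.089. Calls of genes and lists in that fit are not compared with the main fit, since 1 library gives no spread within the controls. In that fit camera's direction changed for the Cajal-Retzius (0.29), microglia (-1.75), erythroid (-0.20) and histone (-0.38) lists. With the hem and Cajal-Retzius score in the fit, 222 genes were called, 70 higher and 152 lower, Insm1 was at 2.40 (adjusted p = 0.0917) and Plekha7 at -0.94 (0.0737), and camera's direction changed for the Cajal-Retzius (-0.061), microglia (-0.83) and histone (-0.27) lists.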

Other observations

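All tests of explanations below were chosen after the results were seen, except the counts over other splits of the libraries.

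Genes of stress, metabolism and organelles were among the lists fixed before the data were seen. Of hypoxia and glycolysis genes 2 of 14 fell, Ndrg1 (3.79-fold) and the lactate dehydrogenase gene Ldha (1.31-fold), or 3 adjusted over the list alone, with a list median of -0.14 (camera adjusted p = 0.00475, lost without control 3 at a median of -0.05 and 0.0754, and adjusted p = 0.444 with an estimated correlation). In the list of unfolded protein and integrated stress response genes 12 of 13 members had a positive log2 fold change, none rose past the threshold, and the serine synthesis gene Psat1 fell 1.98-fold. Adjusted over the list alone 4 were higher and 1 lower, with a median of 0.27 (camera adjusted p = 0.0316, lost without control 1 at 0.0588 or Insm1 library 2 at 0.0748, and adjusted p = 0.274 with an estimated correlation). Of immediate early genes Klf6 and Jun fell 1.63-fold and 1.43-fold, 2 of 15, or 3 lower and 1 higher adjusted over the list alone (median -0.25, from -0.43 to -0.0010 with single libraries left out, camera adjusted p = 0.128, called without control 3 at 0.0407). Among p53 targets none of 13 passed in edgeR, 2 had an unadjusted p below 0.05 and DESeq2 called 1 (median 0.21, camera adjusted p = 0.0334, and adjusted p = 0.274 with an estimated correlation), and the list call was lost without control 2 (0.106), Insm1 library 1 (0.0552) or Insm1 library 2 (0.0650). Nin, which encodes the centrosome protein ninein, fell 2.60-fold, the only 1 of 14 cilium and centrosome genes to pass, also adjusted over the list alone. The median of that list was 0.06, from -0.020 to 0.080 with single libraries left out (camera adjusted p = 0.708). In the cholesterol synthesis list Idi1 fell 1.33-fold, 1 of 15, with 2 higher and 1 lower adjusted over the list alone (median 0.10, camera adjusted p = 0.288). Klf6 and Psat1 were called with each library left out, Ndrg1 and Nin lost the call without control 3, and Jun, Idi1 and Ldha lost it without at least 3 libraries.

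Markers of interneurons and ventral progenitors had a median of -0.83 at low levels, summing to 38.5, 43.3 and 58.9 CPM in controls 1, 2 and 3 and to 27.3 to 32.0 CPM in the Insm1 libraries. Of 12 measured members 1 was called lower, or 3 adjusted over the list alone (camera adjusted p = 0.00834, lost without control 3 at a median of -0.44 and 0.0940, and adjusted p = 0.444 with an estimated correlation). Microglial genes summed to 1.94, 99.7 and 10.3 CPM in controls 1, 2 and 3 and to 13.8, 49.8 and 21.5 CPM in Insm1 libraries 1, 2 and 3 (median -0.38, from -1.11 to 2.04 with single libraries left out, camera adjusted p = 0.477, and called higher without control 2 at a median of 2.04 and 2.31e-06). The remaining lists were not called with all libraries. Medians and camera adjusted p were -0.0023 and 0.461 for cyclin-dependent kinase inhibitors and antiproliferative genes, -0.06 and 0.879 for heat shock genes, -0.06 and 0.917 for endothelial and pericyte genes, and -0.04 and 0.315 for meningeal genes. They were -0.09 and 0.776 for oligodendrocyte lineage genes, 0.02 and 0.649 for mitochondrial transcripts, -0.00014 and 0.649 for ribosomal protein genes, -0.03 and 0.732 for replication-dependent histones, and 0.35 and 0.908 for Y-linked genes. Each of these 9 medians changed sign with at least 1 library left out. Without control 1 the ribosomal list was called (median 0.05, 0.0324), and without control 2 the histone list (median 0.33, 0.0324). Over the 15 lists without a called member, interferon and Cajal-Retzius genes included, 16 of 259 members had an unadjusted p below 0.05 in edgeR, DESeq2 called 7 and limma-voom 0.

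The first pattern is the set of 120 genes called lower by more than 2-fold, among them Grin2b, Mef2c and Dab1, with a median log2 fold change of -1.51. Whether hem and Cajal-Retzius tissue in controls 1 and 3 was the whole cause stays open. With the score of those 2 lists in the fit the median log2 fold was -1.29 and 62 of the 120 genes were still called. These genes were picked as called, and in each of them control 2 lay above all 3 Insm1 libraries. Over the set the median log2 difference, Insm1 minus control 2, was -1.19, which rests on 1 control library. The mean log2 level behind the score ran the other way, at 0.224 in control 2 and 0.549 to 0.743 in the Insm1 libraries. The score could therefore hardly take up the fall, and the fit cannot decide. A kind of cell that was rarer in the Insm1 libraries and also varied between controls may account for part of the fall. Control 2 was the lowest control in 76.7% of the 120 genes against 37.4% of all tested genes, and controls 1 and 3 lay 1.51-fold above it. An effect of the Insm1 plasmid on these transcripts within each cell stays open, since bulk libraries of sorted cells give 1 level per library.

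The second pattern is the interferon list, in which all 12 measured members had a positive log2 fold change (median 1.93, camera adjusted p = 0.000158, and adjusted p = 0.444 with an estimated correlation) while none was called by edgeR, 3 had an unadjusted p below 0.05 and DESeq2 called 1. A single library as the cause is argued against, since without Insm1 library 2 the list median was still 1.21. A state that varies between libraries of the same plasmid is consistent with the levels, since the mean log2 level ranged over 3.18 within the controls and 2.60 within the Insm1 libraries, more than the 2.11 between the group means. Usp18 was at 24.6, 1.07 and 58.9 CPM in controls 1, 2 and 3 and at 111, 130 and 26.0 CPM in Insm1 libraries 1, 2 and 3. An effect of the Insm1 plasmid stays open, as 2 of the 12 members had every Insm1 library above every control and 3 libraries a group are too few to decide.

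The third pattern is the lower level of hem and Cajal-Retzius genes. A difference between libraries, for instance in dissected area, may account for it. The mean log2 level of the 17 measured members ranged over 2.15 within the controls, more than the 0.912 between the group means. That range does not show in what the libraries differed, and dissected area was not recorded in the labels. Control 2, at 0.224, lay below all 3 Insm1 libraries (0.549 to 0.743), and controls 1 and 3 were at 2.38 and 2.16. An effect of the Insm1 plasmid as the only difference, with little spread between libraries, would place every control above every Insm1 library. That order held for 11.8% of the members. Since the spread within the controls was large, this share cannot count against such an effect. In the mean level control 2 alone broke this order. Single members differed, as for Nhlh2 control 3 (51.15 CPM) also lay below the Insm1 libraries (53.65 to 76.85 CPM). An effect on top of differences between libraries need not separate the groups, so it stays open.

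The real grouping of the 6 libraries called 454 genes and the highest of the other splits into 3 and 3 called 0, so 1 of the 10 splits, the real one, gave as many. For lists called the real grouping gave 20 and the highest other 15, again 1 of 10. The other splits, which mix the groups, called from 3 to 15 lists and 0 genes each. Camera at the preset correlation thus called lists also where no gene was called, so a list call alone is weak evidence of a group difference. The 10 splits are too few for a share under 0.05.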
